A study of Mus musculus with 6 samples.

How the data were processed

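RNA was measured in 6 bulk RNA-seq libraries of NG2-tdTomato-positive cells from whole spinal cords of female NG2-CreERTM:Rosa-tdTomato/+:Cx3cr1GFP/+ mice, 3 labelled Control and 3 labelled EAE. Per the labels' protocols, cords from perfused mice were minced and dissociated with enzymes in the presence of actinomycin D, a transcription inhibitor that limits changes in expression during the procedure. Debris was removed, and cells negative for the dead-cell dye Sytox blue and positive for tdTomato were sorted into lysis buffer. RNA was purified with an RNeasy micro kit, samples with an RNA integrity number over 8 were used, and cDNA was made from total RNA with the Ovation RNA-seq System V2. The time between induction of EAE and collection, the time of recombinase induction and any gate on green fluorescent protein are not given in the sources used here. These 6 libraries were all samples of the series, and no other treatment that its title may imply is among them.

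The authors deposited a table of raw read counts, 1 column per library, with 38293 Ensembl gene identifiers, and these values are whole numbers with no normalization. FastQC, STAR, featureCounts, edgeR 3.24.3 and the mouse build mm10 are named per the submitters' processing notes, with no role or order. Aligner settings, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of close paralogs and of overlapping genes, antisense ones included, therefore cannot be separated with certainty, and genes with a near-identical copy, or with at least 5% of their exonic bases in another gene, are named as uncertain where values of them appear and the copy was recognised. Smaller overlaps are not noted. Gene symbols and coordinates came from the GENCODE annotation of GRCm38, matched by Ensembl identifier. Symbols were found for 36345 identifiers (94.9%), 1948 had none, and 12 of the called identifiers were among those without. All rows named a gene, and no column of per-sample values was left out.

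Total counts per library ran from 22141522 to 28734798 reads. Mitochondrial ribosomal RNA took 15.5% to 18.6% of the counts and Malat1 0.935% to 3.05%. At these depths a gene with 0 reads in a library is compatible with up to 3 reads, and this floor of 3 reads per library, 0.128 CPM, set the lower bounds of folds against a group at 0. Genes with 1 to 3 reads in Control are given as a ratio with its exact counting interval. Such intervals and floors cover counting error only, since PCR copies are not independent molecules.

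Groups were taken from the condition in the labels, and the single comparison was EAE against Control. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 16966. Counts were scaled by the trimmed mean of M-values and tested with the quasi-likelihood F test of edgeR with robust dispersion, in R 4.3.3. The test was 2-sided, and p-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The biological coefficient of variation was 39.6%. The printed SE of a log2 fold change is its size divided by the square root of F. CPM and log2 CPM values, with a prior count of 2 for the latter, were computed here from the deposited counts. An exact test of single values in groups of 3 cannot give a 2-sided p under 0.1, so p-values come from models that share information across genes. The median log2 fold change of all tested genes was 0.004, and 0.024 and 0.050 under upper-quartile factors and library sizes alone, so no scaling moved it by 0.1.

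Before the data were examined, 35 gene lists with 658 entries were fixed, 14 of cell type markers and 21 of pathways, along with the test, the alternatives and the rule for named genes. Of 638 distinct list genes 4 had no row in the table. Of the list genes 20 are in more than 1 list, so the lists are not independent. Those called are Vcan in the precursor and matrix lists, Slc2a1 in the endothelial and hypoxia lists, Col6a1 in the fibroblast and matrix lists, Cybb in the myeloid and oxidative lists and Ccl5 in the myeloid and chemokine lists. Each list with 5 or more tested members was tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01, which asks whether its genes rank higher or lower than the other tested genes, with adjustment over 34 lists. Counts of called members are given over all genes and adjusted over the list alone. The fry test, an alternative, asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The difference of medians between pairs of lists was tested by permutation of genes with 100000 resamples, 2-sided.

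Named genes were the 10 called genes with the largest and the 10 with the smallest log2 fold change among those with a mean of at least 10 CPM, group ranges that did not overlap and a symbol that is not a provisional model. Next came up to 4 called members of each list with the smallest adjusted p, or the 2 most abundant members where fewer than 2 were called. Always included were Cspg4, Pdgfra, Cx3cr1, Id1, Id2, Id3 and Id4. Some genes that met the rule are not reported here, although they stayed in all tests and list counts, which left 121 genes. Named beyond this rule, after their values were seen, were Neu4, Klk6, C3, Tgfb2, Dusp1, Mmp2, Ctsb and Bmp4 and the members of families in the closing section.

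Alternatives were RLE factors, upper-quartile factors and library sizes alone, no filter on low counts and a stricter filter of at least 1 CPM in 3 libraries with a mean of 10 counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a threshold of 0.01, glmTreat against a log2 fold change of 1, each library left out in turn, camera with an estimated correlation, fry, and principal components of the 500 most variable genes. Called list members and the folds of called genes without each library, list medians under each scaling and gene families were added after seeing the data. The counting and list tests were tested on simulated data drawn from the means and library sizes of these libraries for 16966 genes, with each gene drawn independently of the others. Of the genes tested that were changed 2-fold, 12 of 99 (12.1%) were recovered, and of those changed 4-fold, 55 of 95 (57.9%). Of 70 genes called, 3 (4.3%) were unchanged. Only 100 genes were changed 2-fold and 100 changed 4-fold, and the real comparison called 1212 genes. With fewer calls the adjusted threshold is stricter for each gene, so these recovery rates may be too low for the real data. A raised list of 20 genes was called and 0 of 30 unchanged lists were. As the simulated genes were not correlated, this cannot show how the preset correlation serves lists of correlated genes.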

Results

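Read counts were obtained from 6 libraries of NG2 lineage cells sorted from mouse spinal cord, 3 from control mice and 3 from mice with experimental autoimmune encephalomyelitis (EAE), an induced autoimmune disease in which immune cells attack central nervous system myelin. The sorted cells were live and carried tdTomato, a red fluorescent protein switched on by an inducible Cre recombinase under the promoter of Cspg4, the gene of the NG2 proteoglycan. That gene is active in oligodendrocyte precursor cells and in the pericytes and smooth muscle cells of vessel walls. All animals were female and carried green fluorescent protein in an allele of Cx3cr1, a chemokine receptor gene of microglia and monocytes. The deposited counts covered 38293 Ensembl genes, and their totals were 25675547, 24190127 and 22141522 reads in Control replicates 1, 2 and 3 and 26220351, 28734798 and 27848034 in EAE replicates 1, 2 and 3. Between 20123 and 22637 genes had a read in a library. The labels do not say whether each library came from 1 animal, so the p-values measure the spread between these samples, part of which may be technical.

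The first principal component of log2 CPM (read counts scaled to the library size) held 46% of the variance and separated the groups, with Control at -58.8, -47.8 and -76.0 and EAE at 44.1, 38.3 and 100.2. EAE replicate 3 thus stood apart from the other EAE libraries on this component, and it also had the lowest share of reads from the nuclear RNA Malat1, 0.935% against 1.94% and 2.62%. Control replicate 3 stood apart on the second component, at -80.5 against 48.2 and 46.4. Pearson correlations of log2 CPM across genes ran from 0.922 to 0.952 within Control, from 0.916 to 0.967 within EAE and from 0.846 to 0.922 between the groups.

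**Figure D1:**
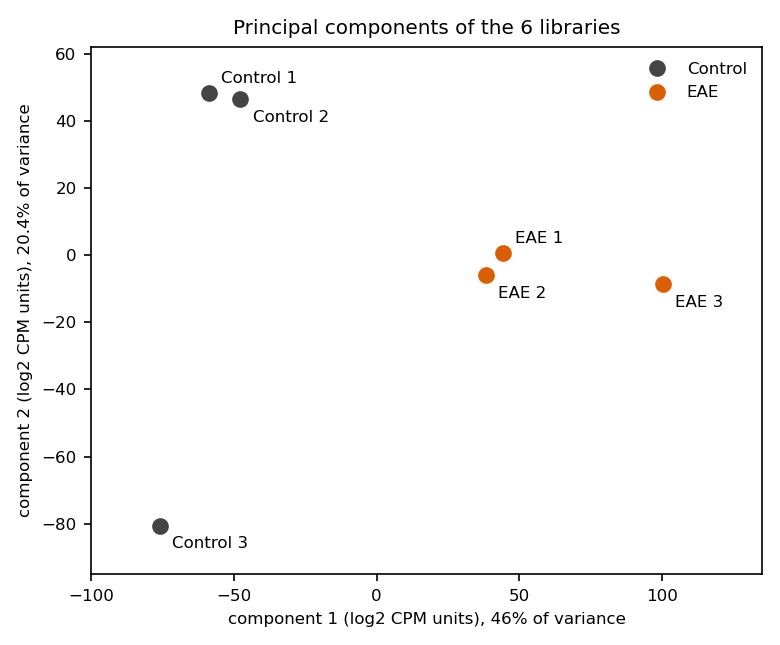
Each point is 1 library placed by its first and second principal components of log2 CPM over 16966 genes (arbitrary log2 CPM units; 46% and 20.4% of the variance). The 3 Control libraries lie at or below -47.8 and the 3 EAE libraries at or above 38.3 on the first component, with EAE replicate 3 at 100.2.

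The comparison of EAE with Control asked how NG2 lineage cells differ in the inflamed spinal cord, in a series whose title concerns BMP receptors, remyelination and the neurovascular unit. By camera, the lists of MHC class I antigen presentation, the interferon response, the cell cycle and newly formed oligodendrocytes were called higher in EAE and those of pericytes, endothelium and cholesterol synthesis lower. All 7 calls were lost with an estimated correlation between genes (adjusted p = 0.210 to 0.455 with an estimated correlation). H2-D1, a class I heavy chain that presents peptides to CD8 T cells, rose 12.9-fold from 70.1 ± 6.28 to 903 ± 46.1 CPM (mean ± SD, n = 3 per group here and throughout; adjusted p = 5.17e-05). Enpp6, a choline phosphodiesterase that marks newly formed oligodendrocytes, rose 4.38-fold (104 ± 22.1 to 458 ± 38.2 CPM, adjusted p = 0.00101), and Pdgfrb, the platelet-derived growth factor receptor of pericytes, fell 6.30-fold (313 ± 81.7 to 49.6 ± 8.84 CPM, adjusted p = 0.00101). The list of genes of mature oligodendrocytes and myelin was not called (median log2 fold change -0.01, camera adjusted p = 0.996).

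By the edgeR quasi-likelihood test, 1212 of 16966 genes passed an adjusted p of 0.05, with 478 higher and 734 lower in EAE. Of these, 1015 had a log2 fold change of 1 or more in size. The number called was 440 without Control replicate 1, 576 without Control replicate 2 and 630 without EAE replicate 1. Among 34 fixed gene lists with 5 or more tested members, camera called 6 higher and 10 lower at a preset correlation between genes of 0.01. With a correlation estimated for each list it called 0, with 4 lists at an unadjusted p under 0.05, and fry called 10 lists, 8 of them among these 16. The fry adjusted p of the other 8 ran from 0.0533 to 0.383.

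**Figure D2:**
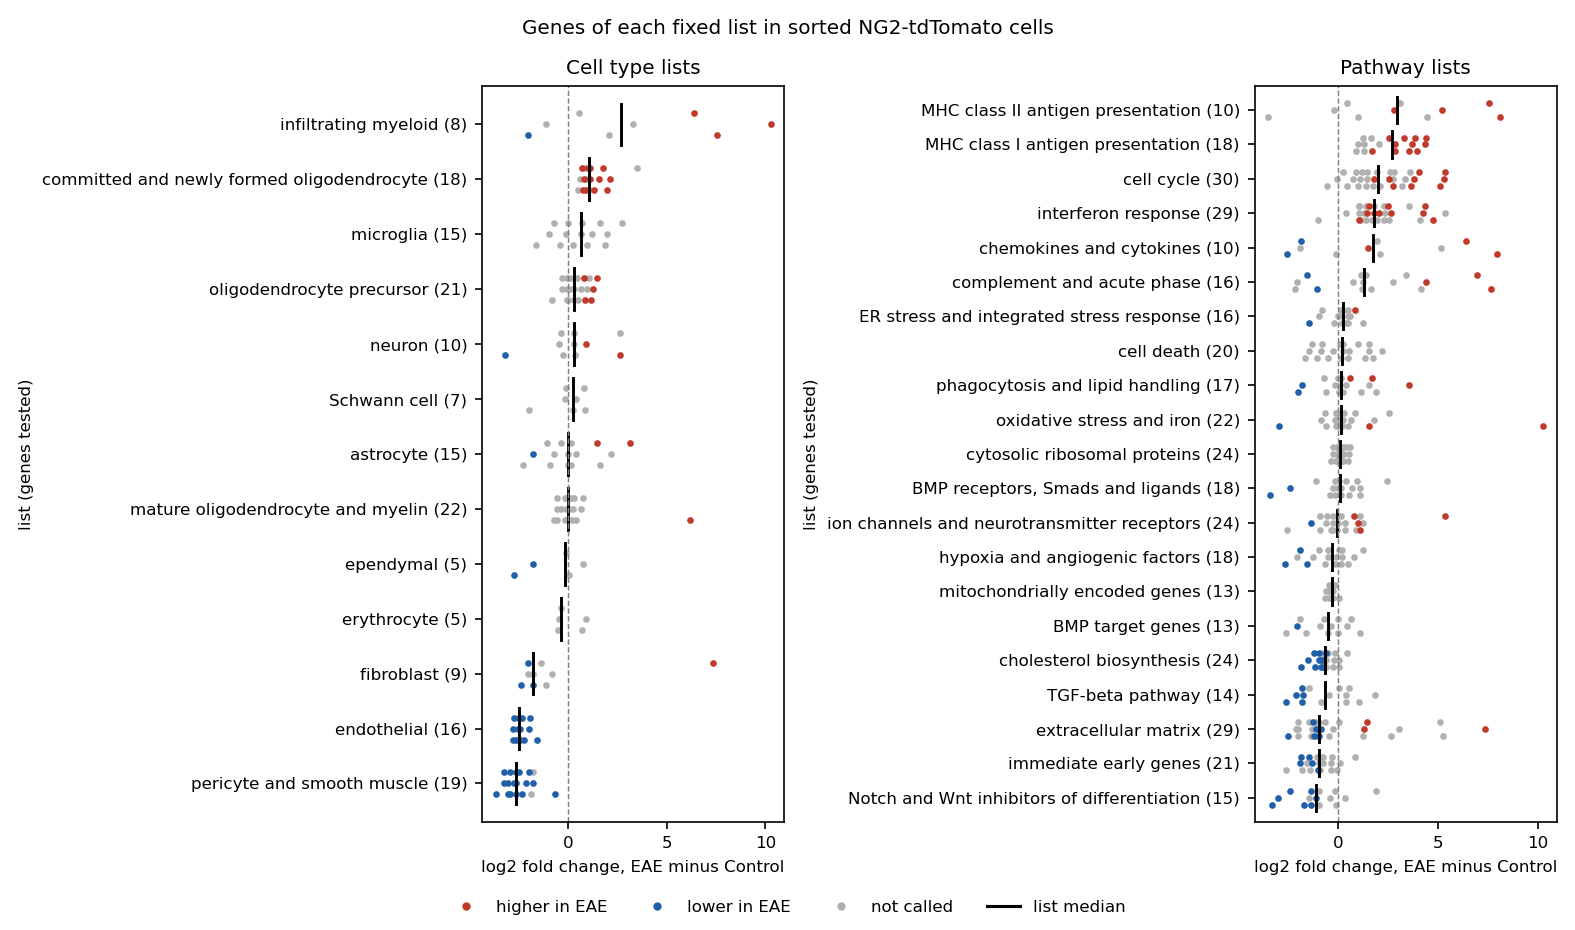
Each point is the log2 fold change (EAE minus Control) of 1 gene of a fixed list, coloured by whether it was called, and each black bar is the median of the list. All 16 endothelial genes lie below 0 around a median of -2.46 and all 18 MHC class I genes above 0 around 2.70; the fitted value of Cybb, which had 0 Control reads, is drawn and is no bound on its change.

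Among abundant genes with the largest increases, Moxd1 (a monooxygenase related to dopamine beta-hydroxylase; ENSMUSG00000020000, chromosome 10, 24223517 to 24302790, GRCm38/mm10) had 0 reads in Control and 1983 in EAE. This made it at least 181-fold higher against a floor of 3 reads per library (adjusted p = 0.00282). Serpina3n, an acute phase protease inhibitor (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), averaged 8.58 ± 3.38 CPM in Control and 1708 ± 2166 CPM in EAE, where replicates 1, 2 and 3 were at 687, 241 and 4196 CPM. Its fold was 199, and 54.5 without EAE replicate 3. The adjusted p of Serpina3n was 0.00755, and up to 0.0585 without Control replicate 1 or 3. The related genes Serpina3g and Serpina3e-ps, the calcium-activated chloride channel regulator Clca3a1, the chemokine Cxcl10 and the lysozyme gene Lyz2 also rose, and all 5 lost their call without each of Control replicates 1, 2 and 3 in turn (adjusted p up to 0.151). Hpgd, a prostaglandin-degrading enzyme, rose 184-fold and was lost without Control replicate 1 or 3 (adjusted p up to 0.0773). The fold of Hpgd was 82.7 without EAE replicate 3 and 439 without Control replicate 2. Values of the Serpina3 genes, Clca3a1 and Lyz2 are uncertain because reads can be shared between close paralogs, and that of Cxcl10 because another gene overlaps 5.9% of its exonic bases. Among genes named for the largest decreases at a mean of at least 10 CPM, those with a call in all 6 fits that each left out 1 library included Alpl, the tissue-nonspecific alkaline phosphatase (12.4-fold, log2 fold change -3.63 ± 0.32, SE here and throughout, adjusted p = 0.00101; ENSMUSG00000028766, chromosome 4, 137741733 to 137796384), and Sox17, a transcription factor of arterial endothelium (10.7-fold, log2 fold change -3.41 ± 0.42). Hmcn1 (hemicentin 1) and the potassium channel gene Kcnj8 fell 10.3-fold and 9.35-fold and also kept their call in all 6 fits. Cox4i2, Map3k7cl and the smooth muscle actin Acta2 fell 20.7-fold, 12.8-fold and 12.7-fold. The call of Cox4i2 was lost without Control replicate 1 or 2 or EAE replicate 2, that of Map3k7cl without Control replicate 1 or 2 or EAE replicate 1, and that of Acta2 without any library other than Control replicate 3 (adjusted p up to 0.0757, 0.108 and 0.0962). Without EAE replicate 1 Cox4i2 was 38.6-fold lower, without Control replicate 2 Map3k7cl and Acta2 were 7.95-fold and 7.08-fold lower, and without EAE replicate 2 Map3k7cl was 22.3-fold lower.

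Within the oligodendrocyte lineage, 12 of 18 genes of committed precursors and newly formed oligodendrocytes rose, and 18 did so when adjusted over the list alone (median log2 fold change 1.05, camera adjusted p = 7.52e-12). The call of this list was lost at adjusted p = 0.210 with an estimated correlation. Enpp6 (ENSMUSG00000038173, chromosome 8, 46986887 to 47096762) had a log2 fold change of 2.13 ± 0.18, Kif19a, a kinesin, 1.97 ± 0.32, and Cnksr3, a signalling scaffold, 1.60 ± 0.22. Tcf7l2, a Wnt effector transcription factor switched on as precursors differentiate, rose 2.18-fold, and these 4 genes kept their call without any 1 library. The number called fell to 5 without Control replicate 1 and 7 without EAE replicate 1. Of 21 precursor genes, 5 rose, namely Vcan and Tnr (matrix proteins of perineuronal nets), the receptor Gpr37l1, the transcription factor Sox6 and the sialidase Neu4, by 2.40-fold, 2.27-fold, 1.79-fold, 2.76-fold and 1.73-fold. Among precursor genes, 8 were higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 0.33 (camera adjusted p = 0.00972, and adjusted p = 0.663 with an estimated correlation). Without Control replicate 1 or 2 no precursor gene was called, and without EAE replicate 1 only 1 was. Sox6 also lost its call without Control replicate 3 or EAE replicate 3 (adjusted p up to 0.0846) and Neu4 without Control replicate 3 or EAE replicate 2 (adjusted p up to 0.141). The camera adjusted p of the precursor list rose to 0.151 without Control replicate 1 and 0.0914 without EAE replicate 3. Cspg4 itself was at 359 ± 14.1 CPM in Control and 206 ± 72.6 in EAE (log2 fold change -0.80 ± 0.23, adjusted p = 0.0764), and Pdgfra, the growth factor receptor of precursors, at 265 ± 95.3 and 332 ± 33.1 CPM (adjusted p = 0.562), so neither passed the test over all genes. Cspg4 was the 1 gene that was lower when adjusted over the list alone. It was at 169, 160 and 290 CPM in EAE replicates 1, 2 and 3. Without EAE replicate 3, 4 precursor genes were called higher and 1 lower. Of 22 genes of mature oligodendrocytes and myelin, only the protease gene Klk6 was called, at a log2 fold change of 6.19 ± 1.30, and 1 was higher when adjusted over the list alone. Klk6 was at 86.0, 42.5 and 725 CPM in EAE replicates 1, 2 and 3. Its fold of 72.8 was 16.5 without EAE replicate 3 and 131 without Control replicate 3. The median of this list was -0.01, its mean 0.26 and its camera direction down (adjusted p = 0.996), and the median turned to 0.01 with upper-quartile scaling and 0.02 with library sizes alone. No mature gene was called without any 1 Control library, 3 were without EAE replicate 2 and 2 without EAE replicate 3. The committed list exceeded the mature list by 1.05 and the precursor list by 0.72 in median log2 fold change (2-sided permutation p = 2e-05 and 0.00023 across genes, Benjamini-Hochberg adjusted 6e-05 and 0.000345 over 3 such comparisons), although genes are not independent replicates.

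Markers of vessel cells were lower in EAE. All 16 endothelial genes fell, also when adjusted over the list alone and in each of the 6 fits without 1 library, with a median log2 fold change of -2.46 (camera adjusted p = 5.59e-19; adjusted p = 0.235 with an estimated correlation). Abcb1a, the efflux pump P-glycoprotein of the blood-brain barrier, whose copy Abcb1b can share reads, fell 5.32-fold from 259 ± 47.6 to 48.6 ± 7.67 CPM (adjusted p = 8.13e-04). Cdh5 (vascular endothelial cadherin), Tek (the angiopoietin receptor) and Ocln (the tight junction protein occludin) fell 5.62-fold, 5.10-fold and 6.57-fold. Among 19 pericyte and smooth muscle genes, 17 fell and 18 did when adjusted over the list alone (median -2.66, camera adjusted p = 2.41e-16, and adjusted p = 0.235 with an estimated correlation). Rgs5, a regulator of G protein signalling abundant in pericytes, fell 6.63-fold from 2761 ± 675 to 416 ± 105 CPM, and Gper1, a membrane oestrogen receptor, fell 8.34-fold. Kcnj8 (ENSMUSG00000030247, chromosome 6, 142564837 to 142571614), which encodes the Kir6.1 channel, and Ndufa4l2 had log2 fold changes of -3.22 ± 0.32 and -3.25 ± 0.51. Leaving out Control replicate 1 reduced the pericyte calls to 11. The medians of the pericyte and endothelial lists differed by -0.20 (2-sided permutation p = 0.154 across genes). Fibroblast genes were sparser, with 9 of 14 tested. The growth factor Igf2, the GABA transporter Slc6a13 and the matrix protein Fbln1 fell 4.03-fold, 5.13-fold and 3.46-fold, whereas Col6a1, a collagen VI chain, rose from 0.0685 ± 0.119 to 12.1 ± 9.47 CPM (adjusted p = 0.00536). In this list 1 gene was higher and 4 were lower when adjusted over the list alone (median -1.75, camera adjusted p = 0.0112, adjusted p = 0.413 with an estimated correlation). Slc6a13 lost its call without Control replicate 1 or 2 or EAE replicate 1 and Fbln1 without Control replicate 1 or 3 or EAE replicate 1 (adjusted p up to 0.0627 and 0.106). The fold of Col6a1 was 162, and 91.6 without EAE replicate 3, and without Control replicate 1 no Control library had a read of it. Without Control replicate 1 or EAE replicate 1 the fibroblast calls fell to 2, and without Control replicate 1 the camera adjusted p was 0.0586.

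**Figure D3:**
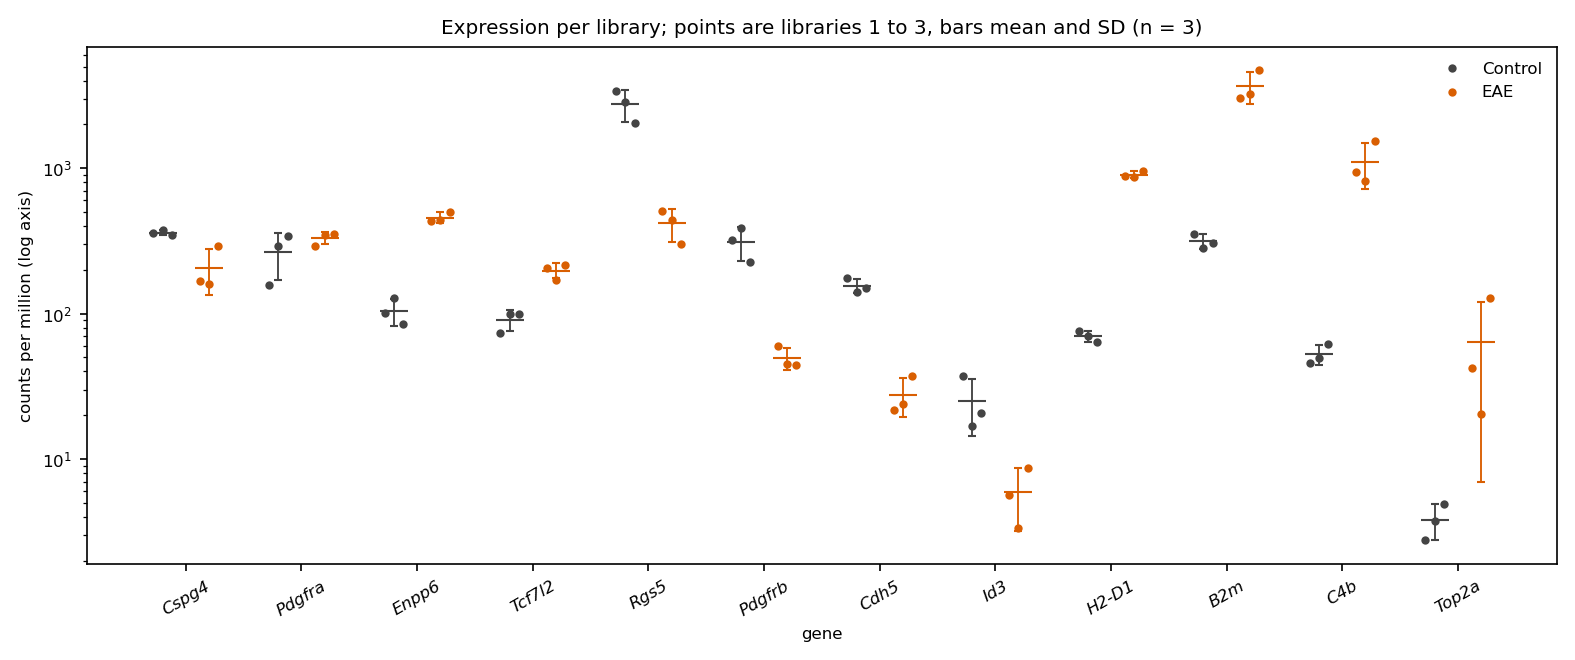
Points are CPM of 12 genes in the 3 libraries of each group on a log axis, with bars at the mean and SD (n = 3). H2-D1 went from 70.1 ± 6.28 CPM in Control to 903 ± 46.1 CPM in EAE and Rgs5 from 2761 ± 675 to 416 ± 105, while the values of Pdgfra overlapped between the groups.

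Of 18 MHC class I genes, 11 rose and all 18 did when adjusted over the list alone (median log2 fold change 2.70, camera adjusted p = 3.53e-14, adjusted p = 0.370 with an estimated correlation). B2m, the class I light chain (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), rose 11.7-fold from 314 ± 36.8 to 3660.2 ± 903 CPM, the heavy chains H2-K1 and H2-Q6 rose 5.83-fold and 14.4-fold, and H2-D1 lies at chromosome 17, 35262730 to 35267499. Values of single heavy chain genes are uncertain, since H2-K1, H2-D1 and the H2-Q genes are near-identical in part and can share reads. The class I calls numbered 7 without Control replicate 1 or Control replicate 3. Interferon response genes rose in 10 of 29 cases and in 23 when adjusted over the list alone (median 1.81, camera adjusted p = 9.55e-11, adjusted p = 0.455 with an estimated correlation), and 4 were called without Control replicate 1, 2 or 3. The fry adjusted p of this list was 0.0881. The GTPase gene Igtp rose 26.6-fold and the mitochondrial protein gene Ifi27 2.73-fold, each with a call in all 6 fits, Igtp at 15.2-fold without EAE replicate 3, although 8% of the exonic bases of Igtp overlap a neighbouring gene. EAE replicate 3, which stood apart on the first component, had the highest EAE value for 29 of 29 interferon and 18 of 18 class I genes, and the median log2 fold changes of EAE replicates 1, 2 and 3 against Control were 1.10, 1.09 and 2.76 for the interferon list. Of 10 MHC class II genes 4 rose, namely the chains H2-Aa and H2-Ab1, the invariant chain Cd74 and the protease Ctss. Their levels were low in Control, with H2-Aa at 0.0939 ± 0.163 against 27.8 ± 31.8 CPM and Cd74 at 0.215 ± 0.372 against 42.7 ± 41.5 CPM. Adjusted over the list alone 6 class II genes were higher and 1 lower (median 2.95, camera adjusted p = 0.00280, adjusted p = 0.455 with an estimated correlation). The list was not called by fry (adjusted p = 0.0981), and limma-voom called 0 of its genes. No class II gene was called without Control replicate 1 or Control replicate 3, and 2 were without Control replicate 2 or EAE replicate 1, while EAE replicate 3 had the highest EAE value for 7 of 10. Ctss and H2-Ab1 also lost their call without Control replicate 2 or EAE replicate 1, and H2-Ab1 without EAE replicate 3 (adjusted p up to 0.115 and 0.144). The folds of H2-Aa and Cd74 were 270.2 and 188, then 93.2 and 87.0 without EAE replicate 3. Control replicate 2 held all Control reads of both, so their folds are not well defined. The myeloid genes Lyz2, Cybb and Tyrobp also rose, with calls lost without Control replicate 1, 2 or 3 for all 3 and without EAE replicate 1 or 3 for Cybb and Tyrobp (adjusted p up to 0.118). Which cells the class II reads came from was not tested.

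Of 20 chemokines and cytokines only 10 were tested. Among these, Ccl5, Cxcl10 and the macrophage growth factor Csf1 rose. Cxcl12, a homeostatic chemokine, and Il34, a ligand of the Csf1 receptor, fell. Ccl5 had 3 Control and 335 EAE reads, a ratio of 94.0 (95% counting interval 31.9 to 458, which covers counting error only). Without Control replicate 2 it had 1 Control read and the ratio was 183 (95% counting interval 32.6 to 7251). Cxcl10 and Il34 share 5.9% and 5% of their exonic bases with other genes, which leaves their values uncertain. Cxcl12 fell 5.94-fold and Csf1 rose 2.77-fold, and adjusted over the list alone 5 genes were higher and 2 lower (median 1.71, camera adjusted p = 0.485). The log2 fold changes of Cxcl12 and Il34 were -2.57 and -1.87, beside medians of -2.46 and -2.66 for the endothelial and pericyte lists. From which cells these 2 changes came was not tested. Without Control replicate 1 or Control replicate 2 the calls fell to 2. Csf1, Il34 and Cxcl10 lost their call in both cases, and Cxcl10 also without Control replicate 3 (adjusted p up to 0.115, 0.0570 and 0.151). The list medians of EAE replicates 1, 2 and 3 against Control were 1.08, -0.28 and 2.27. Of 16 complement and acute phase genes, 3 rose and 2 fell, among them C4b, C3 and Serpina3n, which rose, and Cp (the copper protein ceruloplasmin), which fell 2.08-fold. C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) went from 52.4 ± 8.38 to 1104 ± 388 CPM (adjusted p = 5.08e-04), a value uncertain for reads shared with its copy C4a. With adjustment over the list alone 6 genes of this list were higher and 3 lower (median 1.30, camera adjusted p = 0.0737, which was 0.00238 without EAE replicate 2, 0.454 without EAE replicate 3 and 0.181 without Control replicate 3). Its medians in EAE replicates 1, 2 and 3 were 1.19, -0.01 and 2.52. C3 lost its call without Control replicate 2 (adjusted p = 0.0606) and Serpina3n without Control replicate 1 or 3 (adjusted p up to 0.0585).

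Of 18 infiltrating myeloid genes only 8 were tested. Among these, Lyz2, Ccl5 and Cybb rose and Ly6c2, a close paralog of endothelial Ly6c1 that can share its reads, fell. Adjusted over the list alone 4 were higher and 2 lower (median 2.69, the same with Cybb at its bound, and camera adjusted p = 0.172). With the replicate number as a block the median of this list was 1.57. Cybb, a subunit of the phagocyte NADPH oxidase, had 0 Control reads and was at least 46.7-fold higher, or 9.26-fold without EAE replicate 3. EAE replicate 3 had the highest EAE value for all 8 of these genes, and the list medians of EAE replicates 1, 2 and 3 against Control were 0.44, 0.07 and 3.67. Cybb lost its call without any library other than EAE replicate 2, Lyz2 without Control replicate 1, 2 or 3 and Ly6c2 without Control replicate 1 or 2 or EAE replicate 1 (adjusted p up to 0.118, 0.105 and 0.0639). The myeloid calls fell to 1 without Control replicate 1 or 2 and to 2 without Control replicate 3 or EAE replicate 1, and the camera adjusted p was 0.0453 without EAE replicate 2 and 0.893 without EAE replicate 3. For 15 microglia genes edgeR called 0, with 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (0 adjusted over the list alone, median 0.64, camera adjusted p = 0.650). Without EAE replicate 2 there was 1 microglia call and the camera adjusted p was 0.0453, and the list medians of the 3 EAE libraries were 0.73, -0.54 and 1.15. Sall1, an abundant gene among them, averaged 35.7 ± 3.15 CPM in Control and 26.7 ± 2.93 CPM in EAE (adjusted p = 0.232), and Cx3cr1 0.845 ± 0.761 CPM in Control and 1.01 ± 0.670 CPM in EAE. Only 1 of 19 lymphocyte genes, Ptprcap, had enough reads to test, and it was not called by edgeR, DESeq2 or limma-voom (log2 fold change -0.64 ± 0.82, all of its exonic bases overlapping another gene). Among 15 astrocyte genes, 2 rose and 1 fell, and S100b, which oligodendrocyte lineage cells also express, rose 2.79-fold and Gfap 8.81-fold. Gfap lost its call without Control replicate 2 (adjusted p = 0.0512) and rose 5.16-fold without EAE replicate 3, and adjusted over the list alone 2 genes were higher and 2 lower (median 0.02, camera adjusted p = 0.938). Of 15 neuronal genes 10 were tested. Among these, Tubb3 and Map2, both of microtubules, rose 6.31-fold and 1.86-fold and Stmn2 fell 9.12-fold. Adjusted over the list alone 3 were higher and 1 lower (median 0.30, camera adjusted p = 0.358). No neuronal gene was called without Control replicate 1 or 2, and 1 was without EAE replicate 1. Map2 also lost its call without Control replicate 3 and Stmn2 without EAE replicate 2 or 3 (adjusted p up to 0.140 and 0.154). Tubb3 rose 4.20-fold without EAE replicate 3. Pltp, the phospholipid transfer protein, fell 6.65-fold and Rarres2 (chemerin) 3.36-fold among the 5 of 10 ependymal genes that were tested (1 higher and 2 lower adjusted over the list alone, median -0.12, camera adjusted p = 0.251). The log2 fold change of Pltp was -2.73, beside medians of -2.46 and -2.66 for the endothelial and pericyte lists, and which cells its change came from was not tested. A neighbouring gene overlaps 19.3% of the exonic bases of Pltp and 33.6% of those of Rarres2, and Rarres2 lost its call without Control replicate 1 or 2 or EAE replicate 1 or 2 (adjusted p up to 0.143). For 7 Schwann cell genes (median 0.25, camera adjusted p = 0.395) and 5 erythrocyte genes edgeR called 0, with 0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone. The erythrocyte median was -0.34 and its mean 0.07, with camera upward (adjusted p = 0.938), and the haemoglobin genes Hbb-bs and Hbb-bt, which can share reads, were at 3.52 ± 5.95 and 3.14 ± 5.37 CPM in Control.

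The cell cycle list was called higher in EAE, with 9 of 30 genes called and 21 when adjusted over the list alone (median log2 fold change 2.01, camera adjusted p = 6.76e-11, adjusted p = 0.404 with an estimated correlation). The list was not called by fry (adjusted p = 0.0533), and limma-voom called 0 of its genes. Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose 39.1-fold from 0.358 ± 0.190 to 14.3 ± 13.1 CPM, with 22.8% of its exonic bases overlapping another gene. Top2a, the topoisomerase of dividing cells, rose 16.7-fold to 63.5 ± 56.5 CPM and the proliferation marker Mki67 12.4-fold, but Top2a lost its call without Control replicate 1 (adjusted p = 0.0524) and Mki67 without Control replicate 1, 2 or 3 (adjusted p up to 0.103). EAE replicate 3 had the highest EAE value for 27 of the 30 genes, and without it Ube2c, Top2a and Mki67 rose 18.8-fold, 8.33-fold and 5.55-fold. The list medians of EAE replicates 1, 2 and 3 against Control were 1.805, 1.279 and 3.152, and those of the infiltrating myeloid list, 0.442, 0.067 and 3.671, were also highest in EAE replicate 3. Which cells the cell cycle reads came from was not tested. The number called was 2 without Control replicate 1, 3 without Control replicate 2 or EAE replicate 1, and 4 without Control replicate 3 or EAE replicate 3.

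Cholesterol synthesis genes were lower, with 11 of 24 called and 17 when adjusted over the list alone (median -0.68, camera adjusted p = 6.01e-09, adjusted p = 0.362 with an estimated correlation). Stard4, a sterol carrier, fell 2.92-fold and Insig1, a brake on sterol regulatory element-binding proteins, 2.24-fold. The calls numbered 5 without Control replicate 1 and 3 without Control replicate 2 or EAE replicate 1. Of 17 phagocytosis and lipid handling genes, the cholesterol exporter Abca1, the signalling adaptor Tyrobp and the protease Ctsb rose 3.17-fold, 11.8-fold and 1.52-fold, and another gene overlaps 12.8% of the exonic bases of Ctsb. Mertk and Axl, receptors for apoptotic cell uptake, fell 4.12-fold and 3.54-fold, with 4 higher and 3 lower adjusted over the list alone (median 0.15, camera adjusted p = 0.429). The log2 fold changes of Mertk and Axl were -2.04 and -1.82. They lay between the 5th and 95th percentile of the endothelial and pericyte genes (-3.233 to -1.697). From which cells these 2 changes came was not tested. The calls of this list numbered 2 without Control replicate 1, Control replicate 2 or EAE replicate 1. Tyrobp lost its call without any library other than EAE replicate 2, Ctsb without any other than EAE replicate 3 and Axl without Control replicate 1 or 2 or EAE replicate 1 (adjusted p up to 0.114, 0.139 and 0.0626). Tyrobp rose 7.54-fold without EAE replicate 3.

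The BMP pathway is a subject of the series title. Of 13 BMP target genes only Id3, an inhibitor of basic helix-loop-helix transcription factors (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755), was called, also when adjusted over the list alone. It fell 4.21-fold from 25.0 ± 10.7 to 5.92 ± 2.70 CPM (log2 fold change -2.07 ± 0.42, adjusted p = 0.0208), and its call was lost without Control replicate 1 or EAE replicate 1 (adjusted p up to 0.0917). Id1, Id2 and Id4 had log2 fold changes of -1.91 ± 0.60, 0.45 ± 0.47 and -0.75 ± 0.82 (adjusted p = 0.102, 0.675 and 0.693), and Smad7, a feedback inhibitor, -0.01 ± 0.16. The target list had a median of -0.51 and a camera adjusted p of 0.126, which was 0.0461 without EAE replicate 3. Among 18 BMP receptors, Smads and ligands, Acvrl1, a receptor of endothelial cells, fell 5.29-fold and the ligand Bmp6 fell 10.9-fold, with 5.7% of its exonic bases overlapping another gene. The call of Bmp6 was lost without any 1 library (adjusted p up to 0.187), and the list count was then 1 except without EAE replicate 3, where it was 2, with 1 gene higher and 1 lower. The ligand Bmp4, also in the committed oligodendrocyte list, had a log2 fold change of 1.07 ± 0.28 (adjusted p = 0.0569). Of these genes 1 was higher and 2 were lower when adjusted over the list alone, and the median was 0.06, the mean -0.04, the camera direction up (adjusted p = 0.938) and the fry direction down. Of 14 TGF-beta pathway genes, 5 fell and 7 did when adjusted over the list alone (median -0.68, camera adjusted p = 0.0112, adjusted p = 0.404 with an estimated correlation). They were the co-receptors Tgfbr3 (betaglycan) and Eng (endoglin), which fell 4.31-fold and 6.15-fold, the receptor Tgfbr2 and the ligands Tgfb1 and Tgfb2, which fell 3.59-fold, 3.60-fold and 3.38-fold. The TGF-beta calls numbered 2 without Control replicate 1 or 2 and 3 without EAE replicate 1. Tgfbr2, Tgfb1 and Tgfb2 lost their call without Control replicate 1 or 2, Tgfbr2 and Tgfb1 without EAE replicate 1 and Tgfb1 without EAE replicate 2 (adjusted p up to 0.0895, 0.109 and 0.111). All 35 tested genes of the endothelial and pericyte lists also had log2 fold changes below 0 (medians -2.46 and -2.66), and which cells these changes came from was not tested.

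Genes grouped as Notch and Wnt inhibitors of differentiation fell in 7 of 15 cases, and adjusted over the list alone 9 were lower and 1 higher (median -1.11, camera adjusted p = 3.24e-05, adjusted p = 0.210 with an estimated correlation). Hes1, a repressor induced by Notch (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), fell 10.2-fold from 20.2 ± 6.12 to 1.99 ± 0.371 CPM, Lef1, a transcription factor of the Wnt pathway, fell 5.30-fold and Apcdd1, a Wnt inhibitor, 3.32-fold. The list holds both pathway factors such as Lef1 and inhibitors such as Apcdd1, so its fall gives no direction for Wnt signalling. Whether differentiation was less inhibited cannot be read from it either. The calls numbered 3 without Control replicate 1 or 2 and 4 without EAE replicate 1. Lef1 and Apcdd1 had log2 fold changes of -2.41 ± 0.20 and -1.73 ± 0.20, against medians of -2.46 and -2.66 for the endothelial and pericyte lists, so a change within oligodendrocyte precursors cannot be read from these genes. Immediate early genes fell in 5 of 21 cases, namely Btg2, Klf4, Klf2, Egr1 and Dusp1, and in 11 when adjusted over the list alone (median -0.98, camera adjusted p = 4.31e-06, adjusted p = 0.404 with an estimated correlation). Btg2, an antiproliferative factor, fell 3.64-fold, and Klf4 and Klf2, transcription factors also found in endothelium, fell 3.86-fold and 2.80-fold. Without EAE replicate 1 the count was 3 and Egr1 lost its call (adjusted p = 0.0732), and Dusp1 lost its call without Control replicate 1 or 3 or EAE replicate 1 or 2 (adjusted p up to 0.123). Of 18 hypoxia and angiogenic factors, the endothelial nitric oxide synthase Nos3, the hypoxia-inducible factor Epas1 and the glucose transporter Slc2a1 fell 6.35-fold, 3.82-fold and 2.99-fold, and 32.3% of the exonic bases of Nos3 overlap another gene. These genes are also expressed in endothelium, whose list fell throughout, and which cells the change came from was not tested. Of this list 4 fell when adjusted over the list alone (median -0.33, camera adjusted p = 0.0399, adjusted p = 0.362 with an estimated correlation), and 5 were called without EAE replicate 2. The camera adjusted p of this list was 0.0822 without Control replicate 2, 0.101 without Control replicate 3, 0.120 without EAE replicate 1 and 0.0963 with the replicate number as a block.

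Extracellular matrix genes went both ways, with Col6a1, Vcan and the protease Mmp2 higher and 6 of 29 lower. The laminin chain Lama2 fell 5.71-fold, the proteoglycan Bgn (biglycan) 2.17-fold and the metalloproteinase inhibitor Timp3 2.35-fold, and 21.3% of the exonic bases of Timp3 overlap another gene. The endothelial and pericyte lists also fell, and which cells the matrix changes came from was not tested. Adjusted over the list alone 6 were higher and 14 lower, the median was -0.96, the mean 0.04 and the camera direction down (adjusted p = 0.0173, and adjusted p = 0.663 with an estimated correlation). The camera adjusted p was 0.130 without Control replicate 2 and 0.192 without EAE replicate 2, and EAE replicate 3 had the highest EAE value for 23 of 29. Vcan lost its call without Control replicate 1 or 2 (adjusted p up to 0.0657). The fold of Col6a1 went from 162 to 91.6 without EAE replicate 3, with reads in Control replicate 1 as the only Control reads. Of 24 ion channel and receptor genes, 4 rose and 1 fell, and the glutamate receptor subunits Gria3 and Grik2 rose 2.14-fold and 1.74-fold. Cacng5 rose from 1.32 ± 0.968 to 54.7 ± 75.9 CPM and the calcium channel Cacna1c fell 2.60-fold. Adjusted over the list alone 5 were higher and 2 lower, with a median of -0.06, a mean of 0.16 and an upward camera direction (adjusted p = 0.763), and the calls numbered 2 without Control replicate 1 or 3, 1 without Control replicate 2 and 3 without EAE replicate 1. Cacng5 lost its call without Control replicate 1, 2 or 3, Grik2 without any library other than EAE replicate 1 and Cacna1c without Control replicate 2 or EAE replicate 1 (adjusted p up to 0.158, 0.154 and 0.0740). The fold of Cacng5 was 40.9, 8.33 without EAE replicate 3 and 65.9 without Control replicate 1. In the list of oxidative stress and iron genes, Cybb and the metallothionein Mt2 rose and the iron exporter Slc40a1 fell 7.76-fold among 22, with 4 higher and 2 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.343). None of them was called without Control replicate 1 or 2, and 1 was without Control replicate 3. Mt2 lost its call without Control replicate 3, Slc40a1 without EAE replicate 2 and Cybb without Control replicate 3 or EAE replicate 1 or 3 (adjusted p up to 0.105, 0.0890 and 0.118). Slc40a1 fell 11.8-fold without EAE replicate 1. With all libraries its log2 fold change was -2.96, beside medians of -2.46 and -2.66 for the endothelial and pericyte lists. From which cells this change came was not tested. Of 16 ER stress genes the chaperone Hspa5 rose 1.76-fold and the phosphatase subunit Ppp1r15a fell 2.79-fold, with 2 higher and 1 lower adjusted over the list alone (median 0.21, camera adjusted p = 0.265), and neither was called without Control replicate 1, 2 or 3 or EAE replicate 1, nor Ppp1r15a without EAE replicate 3 (adjusted p up to 0.110 and 0.128).

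For the remaining 3 lists edgeR called 0 genes, also when adjusted over the list alone. Of 20 cell death genes, 5 were at an unadjusted p under 0.05, 4 were called by DESeq2 and 1 by limma-voom (median 0.18, camera adjusted p = 0.938), and 1 was called without EAE replicate 2 or EAE replicate 3. The cell cycle inhibitor Cdkn1a was at 21.2 ± 9.97 CPM in Control and 41.7 ± 15.6 CPM in EAE (adjusted p = 0.216). Of 13 mitochondrially encoded genes, 1 was at an unadjusted p under 0.05 and 0 were called by DESeq2 or limma-voom, while the list as a whole was called lower (median -0.35, camera adjusted p = 0.0266, adjusted p = 0.671 with an estimated correlation). Its camera adjusted p was 0.227 without Control replicate 1, 0.0569 without Control replicate 3 and 0.301 without EAE replicate 3, the library with the lowest EAE value for 12 of the 13. The most abundant, mt-Co1 and mt-Cytb, had log2 fold changes of 0.03 ± 0.23 and -0.18 ± 0.21. Of 24 cytosolic ribosomal protein genes, 1 was at an unadjusted p under 0.05 and 0 were called by DESeq2 or limma-voom (median 0.10, camera adjusted p = 0.429), 1 was called without EAE replicate 2, and Rpl4 and Rpl5 had log2 fold changes of 0.09 ± 0.15 and 0.19 ± 0.16. These values are uncertain, since other genes overlap 7.9% and 26.7% of their exonic bases and pseudogene copies can share reads. In data simulated from these libraries, 12 of 99 tested genes with a true 2-fold change and 55 of 95 with a 4-fold change were called, so a gene without a call can still have changed by such a size. That simulation called 70 genes against 1212 here, so its threshold was stricter and these rates may be too low for the real comparison.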

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

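Called members and folds of called genes without each library, list medians under each scaling and the gene families were chosen only after the result was seen. Against 1212 called genes, RLE factors gave 1217, upper-quartile factors 1220, library sizes alone 1131, no filter 1272, the stricter filter 1257 and limma-voom 990. DESeq2 called 2303, of which 1208 were among the 1212, a threshold of 0.01 left 439 and glmTreat 272; the last 2 are stricter by construction, and for DESeq2 the cause was not tested. Leaving out 1 library, with fewer samples, gave 440 to 1150. With the replicate number as a block 818 genes were called (768 shared) and 16 lists. Same-numbered libraries did not deviate together (correlations of deviations from the group means 0.016, -0.040 and -0.034), the labels do not say what a number stands for, and not every library correlated best with its own number. Under the block camera changed the call of 2 lists (complement 0.0451, hypoxia 0.0963). Against 16 called lists, camera called 0 with an estimated correlation and 13 to 18 without 1 library; fry called 10, namely 8 of the 16 and the neuron and ependymal lists. The first component held 63.3% of the variance of the 500 most variable genes. Of 101 called named genes, 101 passed with RLE or upper-quartile factors, 97 with library sizes, 81 without a filter, 99 of 100 with the stricter filter, 100 of 100 by DESeq2, 82 under the block, 74 by limma-voom and 55 to 92 without 1 library, and none of them changed direction. Signs changed only for values near 0 or with wide errors, and the cause was not tested. Among log2 fold changes, Smad7 became 0.015 and 0.034 with upper-quartile factors and library sizes. Without 1 library the ranges were -0.073 to 0.284 for Cnp, -0.382 to 0.038 for Pllp, -0.135 to 0.489 for Pmp22, -2.386 to 6.21 for Hbb-bs, -2.637 to 6.744 for Hbb-bt, -0.079 to 0.106 for Smad7, -0.156 to 0.319 for Bcl2l1, -0.111 to 0.23 for mt-Co1, -0.01 to 0.171 for Rpl4, -0.296 to 1.04 for Cx3cr1 and -0.121 to 0.69 for Id2. Among list tests, the mature oligodendrocyte list was at an adjusted p of 0.961 under the block and 0.986 with library sizes, and the BMP receptor list at 0.504 by fry. Without 1 library the adjusted p ran from 0.203 to 0.952 for mature oligodendrocytes, from 0.0453 to 0.931 for microglia, from 0.649 to 0.985 for astrocyte, from 0.411 to 0.873 for erythrocyte, from 0.719 to 0.985 for BMP receptors, from 0.456 to 0.985 for cell death, from 0.296 to 0.804 for ion channels and from 0.0711 to 0.851 for ribosomal proteins. Depth limits the weakest genes, and with 3 libraries per group few true 2-fold changes were recovered in simulation (12.1%). The simulation called 70 genes, so its threshold was stricter than that of the real comparison.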

Other observations

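The families of this part and all tests below except the count over other splits were chosen after the result was seen. Of 8 doublecortin and dihydropyrimidinase-like genes, Dcx, a microtubule protein of migrating young neurons, Dpysl3 and Dpysl4 rose 4.99-fold, 3.41-fold and 5.46-fold (adjusted p = 0.00102, 0.00390 and 0.00215), with camera adjusted p = 0.00691 and adjusted p = 0.170 with an estimated correlation. From which cells these reads came was not tested, so they do not show neurons among the sorted cells. Among 14 tubulins, Tubb2a, Tubb2b, Tubb3 and Tubb5 rose 2.71-fold, 3.82-fold, 6.31-fold and 1.86-fold (camera adjusted p = 1.63e-05, adjusted p = 0.260 with an estimated correlation), and 1 was called without Control replicate 1 or 2, 2 without EAE replicate 1 and 7 without EAE replicate 2. Tubb2b kept its call in all 6 fits without 1 library, Tubb2a and Tubb3 lost theirs without Control replicate 1 or 2, Tubb2a also without EAE replicate 1, and Tubb5 without Control replicate 1, 2 or 3 or EAE replicate 1 (adjusted p up to 0.0704, 0.0700 and 0.111), and Tubb3 rose 4.20-fold without EAE replicate 3. Tubb2a and Tubb2b are close copies that can share reads. Of 11 immunity-related GTPases, which act against intracellular microbes, 9 rose (camera adjusted p = 3.62e-09, adjusted p = 0.180 with an estimated correlation), among them Irgm2 (9.42-fold) and Iigp1 (18.7-fold), and Tgtp1 and Tgtp2, which can share reads (7% of the exonic bases of Tgtp1 overlap another gene). EAE replicate 3 had the highest EAE value for all 11, and without it Irgm2 and Iigp1 rose 6.28-fold and 6.74-fold. Iigp1 lost its call without Control replicate 1, 2 or 3 and Tgtp1 without Control replicate 1 or 3 (adjusted p up to 0.0940 and 0.0597), and 6 were called without Control replicate 1 or 3. All 5 Serpina3 genes tested rose (camera adjusted p = 4.69e-06, adjusted p = 0.180 with an estimated correlation), with 0 called without Control replicate 1 or 3, 1 without Control replicate 2 and EAE replicate 3 highest for all 5. Semaphorins and plexins, guidance cues and their receptors, went both ways, with 6 higher, such as Sema3d (3.53-fold) and Sema5a (2.71-fold), and 4 lower, such as Sema3g (7.88-fold) and Sema3c (4.11-fold), of 28 (camera adjusted p = 0.117; 3 called without Control replicate 1, 4 without Control replicate 2 and 6 without EAE replicate 1). Sema5a and Sema3g lost their call without Control replicate 1 or 2, and Sema3g without EAE replicate 1 (adjusted p up to 0.0697 and 0.0842).

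In other families most of the called genes fell. Laminins, basement membrane proteins, fell in 7 of 9 cases, with log2 fold changes of -4.12 ± 0.64 for Lama3 (adjusted p = 0.00680), -2.94 ± 0.35 for Lamc3 (adjusted p = 0.00247) and -2.69 ± 0.29 for Lamb2 (adjusted p = 0.00166). All 5 Zic transcription factors, which mark meningeal and dorsal midline cells, fell, Zic4 by 15.2-fold and Zic1 by 5.10-fold (2 called without Control replicate 1 and 3 without Control replicate 2). Another gene overlaps 6.3% of the exonic bases of Lamc3. Without EAE replicate 1 Lama3 fell 27.6-fold, against 17.4-fold, and Zic4 26.6-fold. Transporters of the Slco, Slc22, Abcb, Abcc and Abcg families fell in 10 of 34 cases, such as the blood-brain barrier carriers Slc22a8 (6.04-fold) and Slco1c1 (6.13-fold), and rose for Slc22a23 (2.28-fold), with 6 called without Control replicate 1. The clock output genes Dbp and Hlf and the clock repressor Nr1d1 fell 3.50-fold, 4.25-fold and 2.98-fold among 16 clock genes (2 called without Control replicate 1, 2 or 3 or EAE replicate 1, and 5 without EAE replicate 3), and Hlf lost its call without Control replicate 1, 2 or 3 or EAE replicate 1 (adjusted p up to 0.111). Other genes overlap 18% and 8.5% of the exonic bases of Dbp and Nr1d1. Camera gave adjusted p = 6e-09, 7.13e-06, 0.00838 and 0.00923 for the laminin, Zic, transporter and clock families, with adjusted p = 0.153, 0.170, 0.180 and 0.305 with an estimated correlation. Of 24 heat shock genes Hspb1 and Hspa1a fell 5.91-fold and 4.43-fold, with 5 lower and 1 higher in all and the value of Hspa1a uncertain for its copy Hspa1b and a gene that overlaps 19% of its exonic bases (camera adjusted p = 0.191, median -0.03, which turned to 0.009 with library sizes alone; 3 called without Control replicate 1 or 2 or EAE replicate 1).

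The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1212 genes, the highest of the other splits 0 (3425 against at most 710 at an unadjusted p under 0.05), and 1 split, the real one, reached 1212. The other splits put libraries of both groups on each side, so any difference between the groups adds to the spread within their sides. Few calls there would follow whatever the cause of that difference, so the counts cannot tell EAE from another cause.

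Pericyte and endothelial genes were lower by a like amount, with a difference of medians of -0.196 (permutation p = 0.154, which does not show that they are equal) and all 35 tested genes of both lists below 0. The scaling of the libraries is argued against as the cause, since a factor per library moves all genes alike, and the median of the list closer to 0 differed by -2.463 from that of all tested genes. A candidate explanation is that fewer vessel cells, or less of their RNA, were among the sorted cells in EAE, as the carriers and laminins that fell could then share 1 source. These families were chosen after the result was seen, so they add no independent support. The Zic genes mark meningeal and dorsal midline cells, so this explanation does not cover them. The label is driven by the Cspg4 promoter, which is not known for endothelium, so how endothelial RNA entered the sorted material was not tested. A lower expression per cell of both classes stays open and was not tested, as cell numbers are not in the counts.

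Genes of committed and newly formed oligodendrocytes were higher while those of mature ones were not. A loss of vessel cells alone would raise all lineage genes alike, but the committed list exceeded the mature list by 1.053 (permutation p = 2e-05, with 100000 resamples of genes, which are not independent replicates). In EAE replicates 1, 2 and 3 the medians against Control were 1.27, 1.13 and 0.88 for the committed list and -0.01, 0.28 and -0.38 for the mature list. These values argue against a loss of vessel cells as the whole cause, provided that both lists were read from the sorted lineage cells, which was not tested. The pattern was also not that of EAE replicate 3 alone, since 13 members were called without it. A larger share of newly formed cells, or higher expression of these genes in precursors, may account for it, and bulk counts of sorted cells do not tell these apart.

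Id3, a BMP target also expressed in vessel cells, was lower at -2.073 (Id1 at -1.91, not called), within the range of -3.233 to -1.697 that holds the 5th to 95th percentile of the 35 vessel genes. Its change could therefore follow the vessel genes rather than BMP signalling in oligodendrocyte lineage cells, a hypothesis that this test, met by values already seen, leaves open.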
